A study of Saccharomyces cerevisiae with 64 samples.

How the data were processed

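Chromatin immunoprecipitation and sequencing of 64 samples were described in the labels, in 9 strains and 42 groups of strain, medium and time, 20 of which had 2 replicates. Per the labels, SK1 diploids were grown in rich medium and then in pre-sporulation medium, moved to potassium acetate medium, fixed with formaldehyde and sonicated, and slow or asynchronous cultures were left out by the authors. Per the labels, reads were aligned by the authors to sacCer3, with BWA and deepTools named without versions. The peak caller, its threshold and any control used in calling are not given in the sources used here. The authors deposited 1 peak list per sample for 62 samples, each peak with its position, its width and a score that is a fraction between 0.5 and 1, deposited as the caller gave it, with no normalization stated. The input and the untagged-strain sample had no peak list and were not analysed here. The lists hold no read counts, so depth is unknown and precision can be given only as counting error over peaks.

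The labels differ in places. Spp1 in the H3 strains is HA-tagged by genotype and antibody but called myc in the sample descriptions, and genotype and antibody were followed. SPS samples are labelled 0 h and were kept apart from SPM 0 h by medium. The catalogue numbers of the myc and GFP antibodies differ between the protocol and the sample fields, and Spp1-myc samples of the competition series carry a genotype homozygous for the myc tag. Peaks on a sequence named chrXVII, under which name the reference has no gene, were counted in peak totals and overlaps and could not be assigned to genes.

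Gene positions (R64) came from the reference table, with 6002 protein-coding genes on 16 nuclear chromosomes. A gene was called occupied when the midpoint of a peak lay in its coding region or within 500 bp upstream. Of 53443 nuclear peaks, 87.5% fell in 1 gene, 7.84% in 2 or more and 4.71% in none. Promoter share was the percent of peaks with a midpoint within 500 bp upstream of a coding start, and convergent share the percent with a midpoint in 1 of the 1513 intervals between genes that face each other. Position within genes of 1000 bp or more was the percent of coding peaks in each of 5 equal parts, a measure added after the data were seen. Overlap was the percent of peaks in the shorter list that share at least 1 bp with the other list. Shares carry Wilson 95% intervals, which cover counting error only. Random placement within chromosomes was drawn 1000 times for overlaps and 100 times for shares (seed 7).

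H3K4R and H3R2A were each compared with wild-type H3 (8 against 8 libraries, permuted within time), 0 h with later times over the H3 strains (6 against 18, permuted within strain) and Spp1-GFP with Spp1-myc at 4.5, 5 and 5.5 h (6 against 6, permuted within time). Tests were two-sided exact permutation tests over all 1296, 21952 or 216 arrangements, and per gene Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over genes with a peak in at least 1 library and a threshold of 0.05. Permutation tests of peak number and of shares were not adjusted for the number of measures. Time courses with 1 library per time were described without tests between times. Replicate numbers were not treated as pairs, and a replicate block was tried as an alternative.

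The 15 gene lists were written from general knowledge of yeast before the data were examined, as were the comparisons, their tests and the rule for naming genes: ribosomal proteins, glycolysis, acetate use, early meiotic, middle and late sporulation, recombination hotspot genes, ribosome biogenesis, translation factors, heat shock and stress, respiration, amino acid biosynthesis, histones, copper, Set1C and the altered loci. Each was tested per library against all coding genes by Fisher's exact test, adjusted over lists and libraries. Tests of occupied members per library, by exact permutation and adjusted over 60 list tests, were added after the data were seen. The genes named were, for tested comparisons, up to 12 passing per direction, ordered by the difference in the share of libraries with a peak, then p, then score percentile, or the 6 first per direction where none passed. In comparisons without replicates they were up to 8 per class by score percentile, and also all altered loci and Set1C genes and up to 4 members of each enriched list. Members of a list that passed, and members counted within a class, were named in addition after their values were seen.

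The per-gene test was tested on simulated data in which 200 genes were changed. It recovered 66.0% of them for H3K4R (0 unchanged genes called), 63.0% for H3R2A (0), 94.5% for 0 h against later (3) and 36.5% for the competition series (0). Each changed gene was given a high probability of a peak in every library of a group and a low one in the other group, without regard to time. The shares recovered therefore hold for large changes present at all times, not for smaller or time-limited ones. Alternatives were the higher-scoring part of each list, lists of equal size, lists without chromosome ends, rDNA and chrXVII, nuclear peaks alone, any overlap in place of the midpoint, promoter windows of 250 and 1000 bp, promoters alone, reciprocal overlap of 50%, peaks widened by 250 bp, a common size of 642 peaks for overlaps, an exact Mantel-Haenszel test, the replicate block, means per replicate number, all 5 competition times and each replicate series left out. Nuclear peaks alone, the common size and the omission of H3R2A replicate 1 at 4 h were chosen after the data were seen. Splits of the libraries were drawn 100 times (seed 11). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.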

Results

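Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map Spp1 and Bre2, subunits of the histone H3 lysine 4 methyltransferase complex Set1C, in budding yeast of the SK1 background, which enters meiosis efficiently. Spp1 carries a PHD finger and a CXXC domain. Cells were sampled in pre-sporulation medium (SPS) and after the shift to sporulation medium (SPM). The peak lists of 62 libraries were used; an input and an untagged-strain sample named in the labels were not analysed here. Spp1-myc, Bre2-myc and Spp1-myc lacking the PHD finger or the CXXC domain had 1 library each in SPS and at 0, 2, 4 and 6 h in SPM, so these 4 strains had no replicates. Spp1-HA was mapped at 0, 2, 4 and 6 h, with 2 libraries per time, in strains whose H3 came from a plasmid as wild type, H3K4R or H3R2A (24 libraries). A competition series mapped Spp1-GFP, expressed from the copper-responsive CUP1 promoter, in 8 libraries and Spp1-myc in 10 libraries between 4.5 and 6.5 h. Lists held 87 to 2119 peaks. Read depth is unknown, because the lists hold no read counts. The labels do not state separate cultures, so p-values measure only the spread between these samples. Without a list from an untagged strain, no background level could be set beside the peaks.

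The genes altered in the strains were examined first. HHT1, which encodes histone H3 and is deleted in the H3 strains per their genotype labels, held a peak in 0 of 24 libraries of those strains (0 of 8 in each) and in 5 of 5 Spp1-myc, 4 of 5 Bre2-myc, 5 of 5 PHD-deleted and 4 of 5 CXXC-deleted libraries. HHT2, the H3 gene also carried on the plasmid, held a peak in 8 of 8 libraries of each H3 strain, in 6 of 8 Spp1-GFP libraries and in 0 of 10 Spp1-myc libraries of the competition series. TRP1, the plasmid marker, held a peak in 8 of 8 libraries of each H3 strain and in 3 of 5 Spp1-myc libraries. The histone H4 genes HHF1 and HHF2 were each occupied in 4 or more of the 5 libraries of every myc strain. LEU2 held a peak in 35 libraries, LYS2 in 20, HIS4 in 14, URA3 in 3 and HO in 1. No library had a peak at SET1, BRE2, SWD2, SHG1, CUP1-1 or CUP1-2. SPP1 itself held a peak in 2 of 8 Spp1-GFP libraries, SWD1 in 3 of 8, SWD3 in 14 libraries across strains and SDC1 in 2.

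The Spp1-myc time course asked where Spp1 sat before and during early meiosis. At 0 h, 2119 peaks were called, against 1163 at 2 h, 1295 at 4 h and 1161 at 6 h. Of 6002 coding genes, 371 held a peak at all 4 times, 990 held one at 0 h and at none of the later times, and 132 gained one at both 4 and 6 h without one in SPS or at 0 h. Persistent genes with the highest-scoring peaks were ALD4 and ICL1, which encode the mitochondrial aldehyde dehydrogenase and isocitrate lyase of acetate use, and the cell wall gene SED1. They also included the ATP synthase gene ATP2, the siderophore transporter gene SIT1, ILV5 of branched-chain amino acid synthesis, the glycolytic gene TDH3 and the carbonic anhydrase gene NCE103. Genes with a peak at 0 h and at no later time, whether or not they had one in SPS, included the chaperone genes SSE1, KAR2 and YDJ1. Among them, too, were BTN2, ZPR1, the ribosomal protein gene RPL3, STP4 and the translation elongation factor gene YEF3. Gained genes included GAP1 and MEP2, which encode the general amino acid and an ammonium permease, INO1 of inositol synthesis, CAR2 and ARG1 of arginine metabolism, the methionine synthase gene MET6, the mitochondrial transporter gene OAC1 and the copper transporter gene CTR3. In sacCer3 coordinates, the 6 h peak in GAP1 spanned chromosome XI 515063 to 516763, within a coding region annotated from 515063 to 516871. The 6 h peak in INO1 spanned chromosome X 134400 to 135900, that in ALD4 chromosome XV 1039850 to 1041050 and that in ICL1 chromosome V 285639 to 286839, all with midpoints in the coding region. The 0 h peak in SSE1 spanned chromosome XVI 350785 to 352235.

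Functional groups divided among these classes. Of 138 ribosomal protein genes, 91 held a Spp1-myc peak at 0 h and at no later time, and 1, RPL15B, held one throughout. The number of occupied ribosomal protein genes went from 107 at 0 h to 2 at 2 h for Spp1-myc, from 130 to 3 for Bre2-myc, from 127 to 1 for PHD-deleted and from 106 to 2 for CXXC-deleted Spp1. Ribosome biogenesis genes were likewise mostly in the 0 h class (22 of 40, among them NOP1 and NSR1), as were translation factor genes (13 of 25, among them TEF2 and SUI2). Persistent occupancy took in 19 of 26 genes of acetate use, the glyoxylate cycle and gluconeogenesis, 14 of 21 of glycolysis, 23 of 35 of respiration and 14 of 34 heat shock and stress genes. It also took in 5 of 11 histone genes, 15 of 50 amino acid biosynthesis genes and 3 of 11 copper genes. Of 36 early meiotic genes, 0 were persistent and 8 were gained: IME1 and IME2, the regulators of meiotic entry, UME6, HED1, ECM11, HOP1 of the chromosome axis, the axis kinase gene MEK1 and the recombinase gene DMC1. Occupied early meiotic genes numbered 0 at 0 h and 16 at 6 h for Spp1-myc, 1 and 17 for Bre2-myc, 1 and 16 for PHD-deleted, and 1 and 19 for CXXC-deleted Spp1. Of 37 middle and late sporulation genes, 0 were persistent or gained. Of 11 genes next to known recombination hotspots, CCT6, ERG25 and ARG4 were persistent. CYS3, BUD23 and DED81 had a peak at 0 h and at no later time.

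Peak by peak, 37.5% of the 0 h Spp1-myc peaks were found at 2 h (Wilson 95% interval 35.4 to 39.6), 37.2% at 4 h (35.2 to 39.3) and 24.8% at 6 h (23.0 to 26.7), against a mean of 6.15% and a maximum of 7.74% in 1000 random placements of the peaks for 6 h. Some 47.5% (45.4 to 49.6) were found at 1 or more later times and 18.2% (16.6 to 19.9) at all 3. Of the 6 h peaks, 54.3% (51.4 to 57.1) were absent at 0 h. The intervals cover counting error only. With lists of equal size, the share found later was 60.3% and the share of 6 h peaks absent at 0 h was 64.8%.

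Within genes of 1000 bp or more, Spp1-myc peaks with a midpoint in the coding region lay mostly near the start at 0 h and in large part near the end at 6 h. With each coding region divided into 5 equal parts, the part at the gene start held 56.8% (54.0 to 59.6) of them at 0 h and 27.3% (23.9 to 31.0) at 6 h. The part at the gene end held 3.46% (2.56 to 4.66) at 0 h, 4.23% at 2 h, 9.74% at 4 h and 38.2% (34.4 to 42.1) at 6 h, where random placement gave 20.1%. At 6 h the end part held 3.66% (2.20 to 6.06) for Bre2-myc, 22.7% (18.9 to 27.0) for PHD-deleted and 12.1% (9.47 to 15.3) for CXXC-deleted Spp1. It held 30.4% and 36.4% in the H3 wild-type libraries of that time, 8.09% and 5.95% in H3K4R and 26.1% and 8.80% in H3R2A. The division of genes into 5 parts was chosen after the data were seen. In SPS, peaks within 500 bp upstream of a coding start made up 18.2% (16.5 to 20.0) for Spp1-myc, against 21.4% at random for that list. They made up 40.3% for Bre2-myc, 37.5% for PHD-deleted and 37.4% for CXXC-deleted Spp1. The Spp1-myc SPS list stood apart in other ways. It held 1782 peaks, against 905, 795 and 910 in the same order. Of its peaks 63.5% were found at 0 h in SPM, against 31.7%, 31.2% and 34.4%. With 1 library each, a difference between proteins cannot be told from one between samples.

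**Figure D1:**
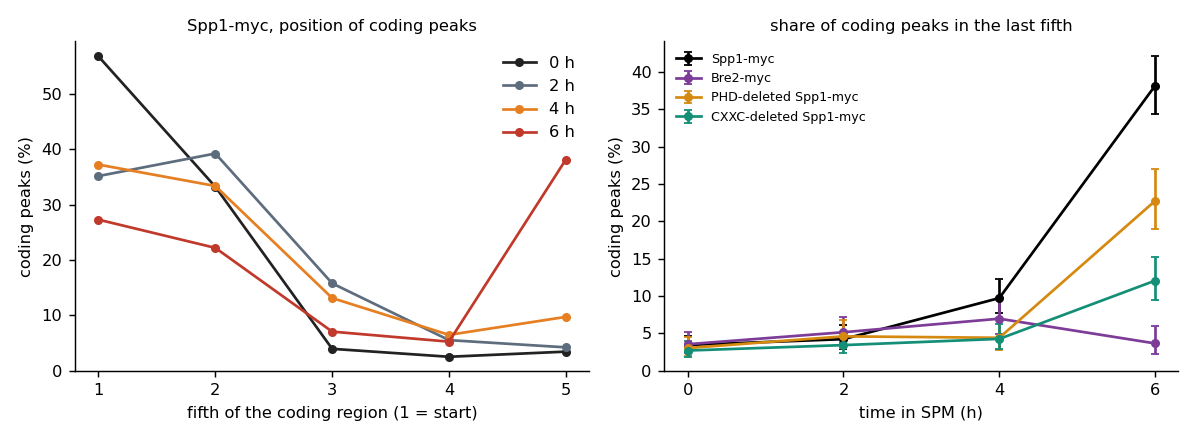
Left, share of Spp1-myc coding peaks (y axis, percent) in each of 5 equal parts of genes of 1000 bp or more (x axis, from the start); right, share in the end part by time in SPM (x axis, hours) in 4 strains, each point 1 library with its Wilson 95% interval. In the end part, Spp1-myc reached 38.2% at 6 h from 3.46% at 0 h, while Bre2-myc was at 3.66% at 6 h.

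Peaks of Bre2 and of the Spp1 domain mutants were set beside those of Spp1-myc at matched stages, to ask whether Spp1 sites are shared with Set1C and need either domain. Of the shorter list in each pair, Bre2-myc peaks overlapped Spp1-myc peaks by 74.3% in SPS and 87.6%, 73.4%, 85.2% and 62.5% at 0, 2, 4 and 6 h. The PHD-deleted protein overlapped by 79.5% in SPS and 88.9%, 78.9%, 85.9% and 76.2%. The CXXC-deleted protein overlapped by 79.8% in SPS and 87.2%, 80.1%, 79.9% and 52.8%. Random placement gave means of 6.17% to 12.1%. Pairs of replicates elsewhere in the series overlapped by 66.1% ± 13.8 (SD, n = 20 pairs), range 47.2 to 89.9, with the low end among competition lists. The 12 pairs of the H3 strains ran from 54.6% to 89.9%, and the CXXC-deleted overlap at 6 h lay below all of them. The 4 H3 wild-type pairs ran from 69.7% to 77.6%, and the Bre2 overlap at 6 h lay below these too. Genes with a Spp1-myc peak at 3 or more of the 4 SPM times and none for Bre2-myc numbered 43, led by STE50, ADE6 of purine synthesis, TDH1, IRC5, CKB1, GET1, IGO1 and the deacetylase gene HST1. The reverse held for 1 gene, YFL064C. The PHD-deleted protein lacked 41 such genes, among them TDH1, CKB1, VID24, RRP7, PCL7, MXR2, CYC7 and GSC2, and SUL2 showed the reverse. The CXXC-deleted protein lacked 15, among them OAC1, TDH1, MXR2, GTA1, IES6, CDC3, FMP48 and KHA1, and ICL2 and HMG2 showed the reverse. Spp1-myc had the longest list of the 4 strains in SPS and at 0, 4 and 6 h, and these gene classes had no test. With every list of these strains and of the H3 strains reduced to 642 peaks, the mean overlaps were 61.6% ± 12.3 for Bre2, 63.8% ± 8.64 for PHD-deleted and 63.3% ± 11.2 for CXXC-deleted protein (SD over 5 stages). The 12 pairs of H3 replicates then overlapped by 59.4% ± 7.18, the lowest by 49.5%. At that size no CXXC-deleted overlap lay below all H3 pairs, since its lowest was 51.4%. The lowest overlaps of Bre2, 46.9%, and of PHD-deleted protein, 49.2%, did lie below the lowest H3 pair at that size. This common size was chosen after the data were seen.

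**Figure D2:**
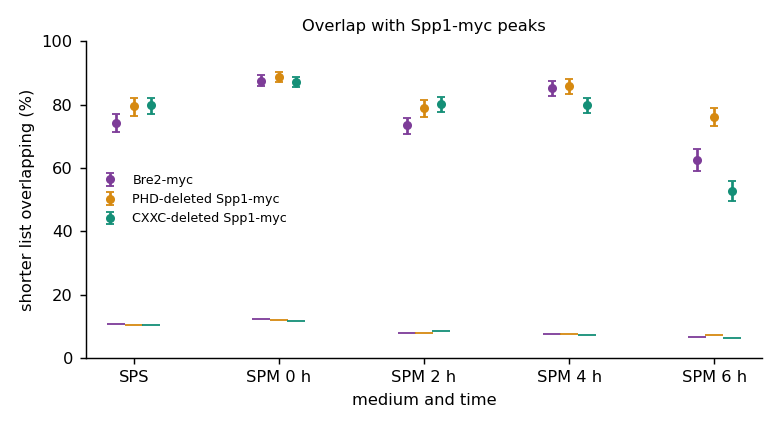
Overlap of peaks (y axis, percent of the shorter list) of Bre2-myc, PHD-deleted and CXXC-deleted Spp1-myc with Spp1-myc at each stage (x axis), as points with Wilson 95% intervals, above short lines that mark the mean of random placements. All 15 overlaps lie between 52.8% and 88.9%.

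H3K4R, in which lysine 4 cannot be methylated, was compared with wild-type H3 over the 4 times. Of the 15 lists, the early meiotic genes had the lowest p. Per H3K4R library, 1.38 ± 0.518 of 36 were occupied (SD, n = 8), against 14.3 ± 10.2 (SD, n = 8) with wild-type H3. The difference was −1.5 genes at 0 h and a mean of −16.7 at the later times. All 32 members with a peak in either strain had it in fewer H3K4R libraries, and the list fell (two-sided exact permutation p = 0.00154, the smallest the 1296 arrangements can give; adjusted p = 0.0463 over 60 list tests). That adjusted p is under 0.05 only because the H3R2A early meiotic test, which used the same wild-type libraries, reached the same smallest p. DMC1, HOP1, IME2 and MEK1 each held a peak in 0 of 8 H3K4R libraries and in 5, 5, 6 and 5 of 8 wild-type libraries. The adjusted p was 0.0686 with the higher-scoring part of each list alone and 0.0556 with a promoter window of 1000 bp, and 0.0649 to 0.0779 with any replicate series left out, where fewer arrangements exist. With replicate number as a block it was 0.0686, again over fewer arrangements. Occupied ribosomal protein genes numbered 66.4 ± 30.8 of 138 against 16.8 ± 36.1, a difference in the other direction that missed the threshold (exact permutation p = 0.0123, adjusted p = 0.0708, n = 8 each). That difference was 33 genes at 0 h and a mean of 55.2 at the later times. Of the wild-type libraries, replicate 1 at 0 h held 106 and the others 2 to 8. Adjusted over the list alone, 4 ribosomal protein genes rose, RPS20, RPS31, RPS15 and RPL5, each in 8 of 8 against 1 of 8 libraries (Fisher's exact test, adjusted p = 0.042). The translation factor gene EFB1 rose (8 of 8 against 1 of 8; Fisher's exact test, adjusted p = 0.0238 adjusted over the list alone) and the chaperone gene SSA2 fell (0 of 8 against 7 of 8; Fisher's exact test, adjusted p = 0.0462 adjusted over the list alone). Middle and late sporulation genes (1.25 ± 1.49 against 9.38 ± 8.25 of 37; exact permutation, adjusted p = 0.0794, n = 8 each) and heat shock genes (13.8 ± 4.98 against 21.8 ± 6.07 of 34; exact permutation, adjusted p = 0.0817, n = 8 each) missed the threshold. Adjusted p for the other 11 lists was 0.117 or more by the exact permutation test. All tests of whole lists were added after the data were seen.

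Over all 3382 genes with a peak, Fisher's exact test with Benjamini-Hochberg adjustment called 0 (197 at an unadjusted p under 0.05; lowest adjusted p = 0.225). The genes first in order, none passing, were MMP1 and RIM8 (8 of 8 H3K4R against 0 of 8 wild-type libraries), YGR161W-C (7 against 0) and RPS15, RPS20 and RPS31 (8 against 1) on the higher side. On the lower side were SLZ1, SSA2 and the transcription regulator gene MOT1 (0 against 7) and the drug pump gene PDR5, CSR1 and the polarity gene SPA2 (1 against 8). Even a split of 8 of 8 against 0 of 8 did not pass, so the count of 0 does not show that no gene changed. The number of peaks did not differ (log2 difference 0.00; two-sided exact permutation p = 1, n = 8 each), nor did the promoter share pass the test (11.5% ± 2.32 against 11.8% ± 3.37; exact permutation p = 0.758). The share between convergent genes was 0.817% ± 0.451 against 0.769% ± 0.313 (exact permutation p = 0.747). The start part of genes held 48.8% ± 6.14 of coding peaks in H3K4R and 37.4% ± 12.4 with wild-type H3 (SD, n = 8; exact permutation p = 0.00926), although p was 0.0741 by the exact permutation test without H3K4R replicate 2. The end part held 5.88% ± 2.96 against 14.1% ± 13.4 (exact permutation p = 0.0648), and p was 0.037 by that exact test without H3K4R replicate 1.

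**Figure D3:**
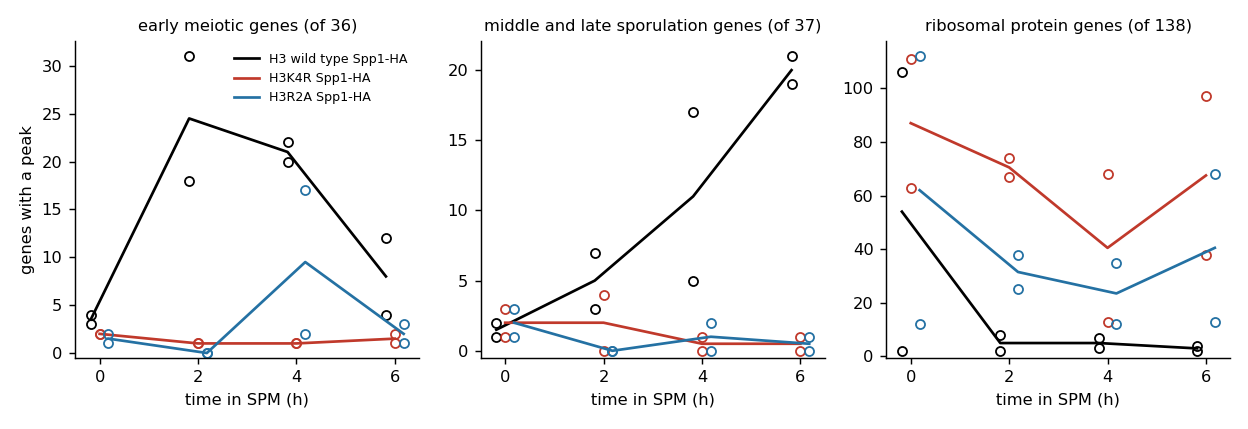
Number of early meiotic, middle and late sporulation, and ribosomal protein genes with a peak (y axes) by time in SPM (x axes, hours) in the 3 H3 strains; each circle is 1 library and lines join the means. Early meiotic genes numbered 1 or 2 in every H3K4R library, and 17 in H3R2A replicate 1 at 4 h.

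H3R2A, in which arginine 2 is replaced, was compared with the same wild-type H3 libraries in the same way. Early meiotic genes were again occupied in fewer libraries: 3.25 ± 5.65 of 36 per H3R2A library against 14.3 ± 10.2 (SD, n = 8 each), lower for all 32 members with a peak. The difference was −2 genes at 0 h and a mean of −14 at the later times. The list fell (two-sided exact permutation p = 0.00154, the smallest possible, adjusted p = 0.0463). It passed only because the H3K4R test shared that smallest p. Without H3R2A replicate 1 at 4 h, which held 17 early meiotic genes where the other 7 held 0 to 3, the difference was −12.9 genes (exact permutation, adjusted p = 0.0463). The adjusted p was 0.0772 at equal list sizes, 0.0779 with the higher-scoring part of each list or with any replicate series left out, and 0.0686 with a promoter window of 250 bp or with replicate number as a block. Middle and late sporulation genes (0.875 ± 1.13 against 9.38 ± 8.25; exact permutation, adjusted p = 0.0686, n = 8 each) and ribosomal protein genes (39.4 ± 34.9 against 16.8 ± 36.1; exact permutation, adjusted p = 0.362, n = 8 each) did not pass. Nor did the other 12 lists (adjusted p of 0.301 or more), and 0 genes of any list passed adjusted over the list alone. Over all 3183 genes with a peak, Fisher's exact test with Benjamini-Hochberg adjustment called 0 (87 at an unadjusted p under 0.05; lowest adjusted p = 0.495). First in order, none passing, were the repressor gene NRG1 and MMP1 (7 of 8 against 0 of 8), RPL3 (8 against 1), RPL10 and RPS2 (8 against 2) and YPL277C (6 against 0) on the higher side. On the lower side were CSR1 (0 against 8), HST1, the cell cycle repressor gene WHI5 and SPA2 (1 against 8), and UTH1 and PDR5 (2 against 8). Even the split of 0 against 8 for CSR1 did not pass, so the count of 0 does not show that no gene changed. The log2 difference in peak number was −0.29 (two-sided exact permutation p = 0.134, n = 8 each), and −0.63 without H3 wild type replicate 2 (exact permutation p = 0.0123). The convergent share passed without H3R2A replicate 1 (difference 0.519 points; exact permutation p = 0.037) and the promoter share without H3 wild type replicate 1 (difference −4.28 points; exact permutation p = 0.037). Promoter share was 9.30% ± 2.37 against 11.8% ± 3.37 (exact permutation p = 0.0833) and convergent share 0.998% ± 0.350 against 0.769% ± 0.313 (exact permutation p = 0.204). The share in the start part of genes was 35.9% ± 10.3 against 37.4% ± 12.4 (exact permutation p = 0.759) and the share in the end part 11.4% ± 7.36 against 14.1% ± 13.4 (exact permutation p = 0.529).

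The shift into sporulation was examined over the 3 H3 strains together, 6 libraries at 0 h against 18 later. Occupancy was higher at 0 h for 235 genes and lower for 24, of 3501 with a peak (Fisher's exact test, Benjamini-Hochberg adjusted; 626 at an unadjusted p under 0.05). Genes occupied in 6 of 6 libraries at 0 h and 0 of 18 later were BAT2 of branched-chain amino acid metabolism, FAT3, the mitochondrial pyruvate carrier gene MPC1, the peptide transporter gene PTR2, USV1, the glycogen synthase gene GSY1, the phosphatase gene PTC3 and YIM1 (Fisher's exact test, adjusted p = 0.00289). MTL1, the respiratory chain gene QCR10, the tRNA splicing gene SEN2 and the vesicle coat gene SEC21 were occupied in 6 of 6 against 1 of 18 (Fisher's exact test, adjusted p = 0.00828). Lower at 0 h were MET5 (0 of 6 against 18 of 18; Fisher's exact test, adjusted p = 0.00289), the methionine pathway genes MET2, MET3 and MET10, and the sulfate permease gene SUL2 (each 1 of 6 against 18 of 18; Fisher's exact test, adjusted p = 0.00969). The hypoxic repressor gene ROX1 (0 against 17), SCM4 (0 against 16), the phosphofructokinase gene PFK1 (1 against 18), the ergosterol genes ERG3 and ERG5 and the protease gene AFG3 (0 against 15) and INO1 (1 against 17) were lower too. With 1 replicate series of a strain left out the count of 259 became 107 (without H3R2A replicate 1) to 147 (without H3 wild type replicate 2), and at equal list sizes it was 61 higher and 37 lower.

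By list, glycolysis had HXK2 and PYK2 higher and PFK1 lower over all genes, and the same with PFK2 lower when adjusted over the list alone. Higher over all genes were also FBP1 and CAT8 of gluconeogenesis, TPS1, GSY1 and GSY2 of the stress list, and the translation factor gene SUI2, and each of these passed adjusted over the list alone as well. LEU1 and MET3 of amino acid biosynthesis were lower both ways, while that list as a whole did not pass (exact permutation, adjusted p = 0.589). RPL7A, RPL27A and RPS22B, and the early meiotic gene REC107, were higher over all genes, while 0 ribosomal protein and 0 early meiotic genes passed adjusted over the list alone. No list passed as a whole by the exact permutation test. Ribosomal protein genes numbered 67.7 ± 50.5 at 0 h and 31.9 ± 30.4 later (adjusted p = 0.0817, exact permutation, n = 6 and 18). There were 106 in H3 wild type replicate 1 and 2 in replicate 2 at 0 h. Genes of acetate use (25.2 ± 0.753 against 21.6 ± 2.73) and translation factors (11.3 ± 4.84 against 6.33 ± 3.05) each had an adjusted p of 0.0686 by the exact permutation test. Early meiotic genes numbered 2.33 ± 1.03 against 7.61 ± 9.70 (exact permutation, adjusted p = 0.274, n = 6 and 18). The remaining lists had adjusted p of 0.0708 or more, by the exact permutation test.

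Peak lists were longer at 0 h (log2 difference 0.54, a ratio of 1.46; two-sided exact permutation p = 0.0114, n = 6 and 18). The promoter share was 8.72% ± 0.891 at 0 h and 11.6% ± 2.93 later (exact permutation p = 0.0215), but the difference of −2.85 points became 1.64 when any overlap counted and 3.08 with a window of 1000 bp. Convergent intergenic peaks made up 1.16% ± 0.322 against 0.763% ± 0.342 (exact permutation p = 0.0215). The start part of genes held 48.0% ± 7.63 of coding peaks at 0 h and 38.3% ± 11.3 later (exact permutation p = 0.0355), and the end part 3.95% ± 1.23 against 12.6% ± 9.82 (exact permutation p = 0.0267). By the exact permutation test, the promoter share missed the threshold without H3 wild type replicate 2 (p = 0.0781) or H3R2A replicate 2 (p = 0.0759), and the convergent share without H3 wild type replicate 1 (p = 0.123), H3K4R replicate 1 (p = 0.0915) or H3K4R replicate 2 (p = 0.0733). The start-part share missed it without replicate 1 of H3 wild type (p = 0.326), H3K4R (p = 0.0686) or H3R2A (p = 0.114), and at equal list sizes (p = 0.375, all exact permutation). The end-part share missed it without H3 wild type replicate 1 (p = 0.089), H3 wild type replicate 2 (p = 0.136) or H3R2A replicate 1 (p = 0.0536, exact permutation).

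The competition series set Spp1-GFP from the CUP1 promoter beside Spp1-myc at 4.5, 5 and 5.5 h, where both tags had 2 libraries. By genotype label the Spp1-GFP samples carry both tags and the Spp1-myc samples are homozygous for the myc tag. Whether both tags were in the same cells is therefore not settled, and a difference between the tags cannot be separated from one between strains. The labels alone do not show exchange of Spp1 on chromatin. Spp1-GFP lists were longer, with 348 ± 220 peaks against 122.0 ± 24.9 (SD, n = 6). The log2 difference was 1.31, a ratio of 2.48 (two-sided exact permutation p = 0.00926, the smallest the 216 arrangements can give). The gap was widest at 4.5 h, with 530 and 705 peaks against 134 and 96. It was 260 and 254 against 166 and 106 at 5 h, and 181 and 155 against 114 and 116 at 5.5 h. All occupied genes numbered 292 ± 216 for Spp1-GFP and 60.7 ± 23.0 for Spp1-myc, so counts of list members may also reflect longer lists. Occupied middle and late sporulation genes numbered 9.83 ± 3.97 of 37 against 2.00 ± 1.79, and early meiotic genes 10.0 ± 9.78 of 36 against 0.833 ± 0.753. There were respiration genes 11 ± 11.1 of 35 against 1.00 ± 1.26, genes of acetate use 10.7 ± 6.38 of 26 against 4.17 ± 2.14 and histone genes 3.83 ± 3.66 of 11 against 0. None of these lists passed (exact permutation, adjusted p = 0.0794, 0.0794, 0.0686, 0.0686 and 0.0686, n = 6 each), nor did the other 10, in a design where adjustment over 60 tests leaves little room below 0.05. Adjusted over the list alone, the sporulation septin gene SPR3 held a peak more often (6 of 6 against 0 of 6, Fisher's exact test, adjusted p = 0.039). So did HHT2 among histone genes (Fisher's exact test, adjusted p = 0.0195) and among the altered loci (Fisher's exact test, adjusted p = 0.0152). Spp1-GFP lists were longer, and these calls were not repeated at equal list sizes. Over all 870 genes with a peak, Fisher's exact test with Benjamini-Hochberg adjustment called 0 (29 at an unadjusted p under 0.05; lowest adjusted p = 0.171). With all 5 times it called 9, all higher for Spp1-GFP. At 3 times, even a split of 6 of 6 against 0 of 6 did not pass, so the count of 0 does not show that no gene changed. First in order at 3 times, none passing, were the spore wall gene LDS2, the acyl-CoA-binding gene ACB1, HHT2, the cap-binding gene STO1, SPR3 and the spindle pole body gene BBP1 (6 of 6 against 0 of 6). On the lower side were the invertase gene SUC2, the flocculin gene FLO1, the repressor gene XBP1, SAM3, HPF1 and SOF1 (0 of 6 against 3 of 6).

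Peaks of the tags lay in different parts of genes. The start part of genes held 60.0% ± 3.91 of coding peaks for Spp1-GFP and 25.4% ± 5.96 for Spp1-myc, and the end part 6.97% ± 1.62 against 34.0% ± 9.0 (SD, n = 6; two-sided exact permutation p = 0.00926 for both, the smallest possible). The promoter share of all peaks was 16.0% ± 3.62 against 5.43% ± 2.07 (exact permutation p = 0.00926), and the difference was 4.17 points at equal list sizes (exact permutation p = 0.102). That share counts peaks on the sequence named chrXVII, which were 18.1% ± 12.0 of Spp1-GFP and 44.3% ± 6.76 of Spp1-myc peaks. Of nuclear peaks, promoters held 19.7% ± 4.75 against 9.94% ± 4.13, a difference of 9.80 points (exact permutation p = 0.00926, chosen after the data were seen). Convergent intergenic peaks made up 1.68% ± 0.786 against 0.830% ± 0.789 (exact permutation p = 0.0926), a test added after the data were seen. Peaks on nuclear chromosomes numbered 302 ± 225 for Spp1-GFP and 69.2 ± 22.6 for Spp1-myc. Against the Spp1-myc time course at 4 and 6 h, competition peaks overlapped by 52.2% ± 8.73 (SD over 36 pairs of lists, which share libraries), against random means of 6.31% to 15.1%. The mean depended on the setting: it was 42.5% with nuclear peaks alone, 32.3% with the higher-scoring part of each list and 29.6% with reciprocal overlap of 50%. With every list reduced to the size of the shortest it was 11.1%, and random placement was not drawn at that size.

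**Figure D4:**
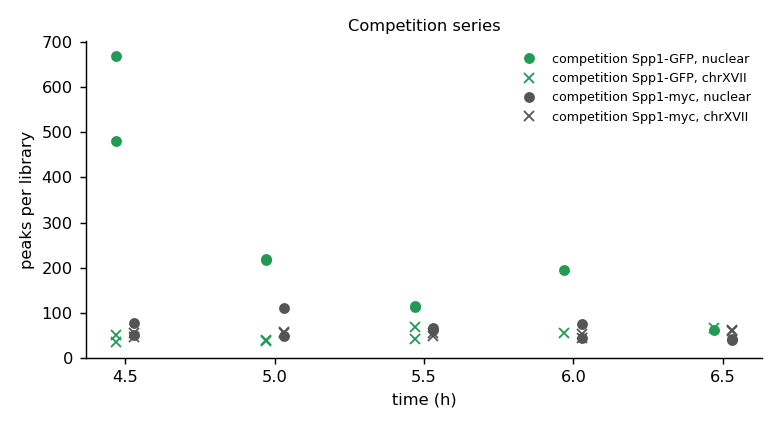
Peaks per library (y axis) by time in SPM (x axis, hours) in the competition series, with circles for peaks on the nuclear chromosomes and crosses for those on the sequence named chrXVII; each symbol is 1 library. Nuclear peaks numbered up to 670 for Spp1-GFP at 4.5 h and 62 at 6.5 h, and 40 to 110 for Spp1-myc.

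Across all 62 libraries, the lists of genes occupied more often than all coding genes were those of acetate use (58 libraries, Fisher's exact test, adjusted), heat shock and stress (51), respiration (48), histones (44), glycolysis (42) and amino acid biosynthesis (38). ACS1, the acetyl-CoA synthetase gene, held a peak in 57 libraries, the polyubiquitin gene UBI4 in 59 and the superoxide dismutase gene SOD1 in 51. The altered loci were enriched in 26 libraries, hotspot genes in 25, copper genes in 12, translation factors in 11 and Set1C genes in 2. Ribosomal protein genes were enriched in 16 libraries and depleted in 19, early meiotic genes in 13 and 14, middle and late sporulation genes in 15 and 27, and ribosome biogenesis genes in 3 and 13. These were 404 enriched and 73 depleted calls. With promoters alone, which keep fewer peaks, the same test made 24 calls, all enriched. No control with equally few peaks was run, so the counts do not tell promoter from coding peaks. Genes are not independent replicates, so these calls describe each library.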

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

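The values below without chrXVII come from an alternative chosen after the data were seen. Peaks on the sequence named chrXVII, which enters no comparison of genes, made up 22.8% of peaks in the Spp1-GFP libraries of the competition series, 47.7% in its Spp1-myc libraries and 3.92% in the other 44 libraries. They stand out because the labels do not say what that sequence is and no untagged list was available to set beside them. The reference has no gene under that name. It lists 46 genes of the mitochondrial genome, the last ending at position 85777, and the last chrXVII peak ended at 85150. If chrXVII is the mitochondrial genome, these peaks are not sites of Spp1 or Bre2 on nuclear chromatin. Their number differed less than their share: 49.3 ± 13.2 (SD, n = 8) for Spp1-GFP, 53.4 ± 5.83 (SD, n = 10) for Spp1-myc and 42.3 ± 14.7 (SD, n = 44) elsewhere, so the shares follow mainly from the number of nuclear peaks. With nuclear peaks alone, the overlap of competition lists with Spp1-myc at 4 and 6 h was 42.5% in place of 52.2%. No explanation of the chrXVII peaks was tested.

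Whether the strain differences at 0 h differed from those at later times was tested for 40 measures by exact permutation, and none passed (lowest adjusted p = 0.262). With 1296 arrangements and 40 tests, no measure could pass by itself, so this does not show equal differences at all times. Early meiotic differences were −1.5 genes at 0 h and −16.7 later for H3K4R, and −2 and −14 for H3R2A (exact permutation, adjusted p = 0.262 and 0.340). Groups of strain, medium and time held at most 2 libraries, and the test used for single libraries needs at least 4, so none was run within groups.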

How the results depend on the processing

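Position in genes, whole-list tests, nuclear peaks alone, the common list size of 642 and the omission of H3R2A replicate 1 at 4 h were chosen after the data were seen. Of the alternative values for main results, 255 kept their direction and their side of the threshold, or stayed within the spread, 40 moved, 17 reversed, 32 lost significance and 5 gained it. For named lists that missed the threshold in the main tests, 119 kept both, 1 reversed and 1 gained significance. The early meiotic lists of H3K4R and H3R2A, which passed, are counted among the main results. The cause was not tested for any change below, except where fewer libraries leave fewer arrangements.

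With a replicate block (replicate number as a stratum beside time or strain), the early meiotic differences stayed at −12.9 for H3K4R and −11 for H3R2A (adjusted p = 0.0686 for both, exact permutation with fewer arrangements), and 0 h calls numbered 206. To look for pairing, the deviations of replicates in gene occupancy, taken within each strain and time, were correlated between groups. These correlations of deviations, not of occupancy itself, were −0.0784 to 0.187 (mean 0.0364) between times of a strain. Between strains at a time they were −0.181 to 0.227 (mean 0.0185), and between competition tags the mean was −0.017. The labels state no pairing, and it was not used in the main tests, although deviations at some H3R2A and H3 wild type times correlated by up to 0.187. With the mean per replicate number as the unit, the H3K4R start-part difference was 11.5 points (exact permutation p = 0.333, a design of 2 against 2 that cannot pass).

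Any overlap in place of the midpoint turned the promoter difference from −0.37 to 2.60 for H3K4R and from −2.85 to 1.64 for 0 h, and gave convergent differences of 0.601 for 0 h (exact permutation p = 0.0969) and 1.98 for Spp1-GFP (exact permutation p = 0.0278). A 1000 bp promoter window gave 0.935 for H3K4R, 3.08 for 0 h and an H3K4R early meiotic difference of −12.1 (exact permutation, adjusted p = 0.0556). A 250 bp window gave −10.8 early meiotic genes for H3R2A (exact permutation, adjusted p = 0.0686). With promoters alone, which keep fewer peaks, lists per library gave 24 calls in place of 477, and no control of equal size was run.

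At equal list sizes the start-part difference was 0.922 for H3R2A and 3.41 for 0 h, the H3R2A early meiotic difference −8.13, 0 h calls 98, and for Spp1-GFP the promoter difference 4.17 and the ribosomal protein difference −0.167. The share of 0 h Spp1-myc peaks found later was 60.3% and of 6 h peaks absent at 0 h 64.8%, and overlaps were 62.1% for Bre2, 64.7% for PHD-deleted, 65.4% for CXXC-deleted, 11.1% for the competition and 49.4% for replicate pairs. These sizes differed (765, 772, 910, 87 and 87 peaks), so the overlaps are not comparable with each other. With 642 peaks in every list they were 61.6%, 63.8% and 63.3% for the first 3 and 59.4% for H3 replicate pairs. With the higher-scoring part of each list, early meiotic differences were −9 for H3K4R and −7.63 for H3R2A, the 0 h start-part difference 7.76, 0 h calls 160, 6 h peaks absent at 0 h 57.5%, and overlaps 75.1%, 79.1%, 73.0% and 32.3% for Bre2, PHD-deleted, CXXC-deleted and competition.

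Reciprocal overlap of 50% gave 36.5% for 0 h peaks found later, 72.4% for 6 h peaks absent at 0 h, and overlaps of 57.2%, 60.2%, 58.5% and 29.6% in the same order, with 49.7% for replicate pairs. Peaks widened by 250 bp gave 51.9%, 49.1%, 81.9%, 86.2%, 81.2% and 63.6% for the first 6 of these. Without chromosome ends, rDNA and chrXVII the competition overlap was 43.7%, and the H3K4R log2 peak difference −0.0138. With nuclear peaks alone they were 42.5% and −0.0101. With all 5 times, Spp1-GFP had 9 genes called.

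With 1 replicate series left out, H3K4R differences ranged from −0.34 to 0.34 for log2 peaks, −2.12 to 1.38 for promoter, −0.117 to 0.214 for convergent, 9.0 to 13.9 for start-part and −10.3 to −6.10 for end-part shares, and −13.6 to −12.1 for early meiotic genes. H3R2A differences ranged from −0.63 to 0.0408, −4.28 to −0.786, −0.0597 to 0.519, −4.70 to 1.84, −6.17 to 0.763 and −12.5 to −9.50 in the same order. For 0 h they ranged from −3.75 to −1.95 for promoter, 0.311 to 0.478 for convergent, 6.56 to 12.8 for start-part and −10.6 to −6.78 for end-part shares, and 107 to 147 genes were called. Leaving out H3R2A replicate 1 at 4 h moved no share, peak number or list across the threshold, and 206 genes were called at 0 h in place of 259. Depth is unknown, so the effect of sequencing depth on any list could not be assessed.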

Other observations

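The tests of splits for the 3 comparisons with no called gene and of list length for H3R2A were chosen only after the result was seen, as were the whole-list tests and the division of genes into parts. Of the genes with an end-part Spp1-myc peak at 6 h, 92.6% (88.4 to 95.3) had a convergent neighbour, against 50.3% (42.7 to 57.9) of those with a start-part peak and 50.5% of all genes of 1000 bp or more, a difference of 42.3 points. Length of the list was argued against, since the end-part share at 6 h was 36.1 points above that at 0 h at equal list sizes (38.2% against 2.04%). A change of genes cannot be the whole of it, because among 276 genes with a coding peak at both times it was 15.8 points above (20.5% against 4.61%). The intervals between convergent genes held 0.519% (0.290 to 0.927) of Spp1-myc peaks at 0 h and 3.36% (2.47 to 4.56) at 6 h, against 4.32% and 4.30% at random, but in H3 wild type 0.872% and 0.828% at 0 h and 0.707% and 1.09% at 6 h. A candidate explanation is Spp1 signal tied to convergent neighbours, but no technical bias of peak calling at such sites was tested and the strain had 1 library per time.

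Early meiotic genes were seldom occupied with H3K4R and H3R2A, among them DMC1, HOP1 and IME2. H3K4R lists were not shorter than wild-type lists on average (log2 difference 0.00), so a cut to equal size had little to test there. In H3R2A, where that difference was −0.29, shorter lists are argued against as the whole cause. H3K4R and H3R2A libraries held 1.38 ± 0.518 and 3.25 ± 5.65 such genes against 14.3 ± 10.2 in wild type. At 642 peaks per list these were 0.625 ± 0.744 and 2.38 ± 4.75 against 10.5 ± 8.83 (SD, n = 8 each, exact permutation p = 0.00154 and 0.00772, unadjusted). Adjusted over 60 tests, the exact permutation p at equal list sizes was 0.0463 for H3K4R and 0.0772 for H3R2A (difference −8.13 genes). The adjusted call ended for H3R2A because its p was no longer the smallest possible. Each was adjusted with the other comparisons at full list size, so the H3K4R call rests on the H3R2A result at that size. At 4 and 6 h, H3K4R lists overlapped wild-type 0 h lists by 45.7% ± 4.39 and matched-time lists by 37.2% ± 11.1 (SD, n = 8 pairs each, which share libraries). The difference of 8.53 points had the direction predicted beforehand for slower progress. It was smaller than the larger SD between single pairs, 11.1, and was therefore not taken to decide. H3R2A lists overlapped wild-type 0 h lists by 43.9% ± 7.96 and matched-time lists by 44.9% ± 16.8. The H3R2A values include replicate 1 at 4 h, which overlapped the wild-type 4 h lists by 77.4% and 56.5% and the 0 h lists by 40.3% and 48.4%. The matched-time mean for H3R2A therefore rests in part on that library. Slower progress into meiosis in the mutant strains therefore stays possible and cannot be told apart from an effect of the substitutions on Spp1, which was not tested. Ribosomal protein genes, occupied mostly at 0 h in Spp1-myc, bear on this too. At later times, occupied members exceeded wild type by a mean of 55.2 in H3K4R and 27.5 in H3R2A. Neither list difference passed adjustment over all times by exact permutation, so these values do not settle it.

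H3R2A replicate 1 at 4 h held 17 early meiotic genes, where the other 7 H3R2A libraries held 0 to 3. A longer list was argued against, since at equal list sizes it still held 14, against at most 2 in the others. It overlapped the wild-type 4 h lists by 77.4% and 56.5%, at least 4.67 points above its highest overlap with another H3R2A list (51.9%), so a wrong label or a mixed sample may explain it. Overlaps with wild-type 2 h lists were 68.8% and 63.6%, and real variation in meiotic timing between cultures stays open and was not tested.

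Other splits of the same libraries were counted for the genes called. For 0 h against later times, 259 genes were called and the highest of the other splits gave 0. Of 100 splits, only 1, the real one, was as large, so a random grouping of these libraries is unlikely to call as many genes. The splits ignored strain and took libraries as independent. Shared cultures and the longer lists at 0 h (a ratio of 1.46) therefore stay possible as contributors. For H3K4R, H3R2A and the competition series 0 genes were called, so 100 of 100 splits gave as many (highest other 0) whatever the data, and the count says nothing about chance.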
